A study of Mus musculus with 48 samples.

How the data were processed

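RNA sequencing of mouse cortex and of samples titled NPC was deposited as 4 tables of FPKM per gene, and the authors made these fpkm values scaled to gene length and to the mapped fragments of the library. The submitters' processing notes name Trim Galore 0.6.5, STAR 2.5.3a, featureCounts 2.0.4 and the mm10 genome, with no role for each. RNA was extracted with TRIzol and libraries were made with a NEB Next Ultra RNA kit, per the labels, and whether poly(A) RNA was selected is not stated. The tables held 54100 genes in 20 libraries (P1, P7, P14 and P45), 55401 genes in 15 libraries (P21), 48785 genes in 6 libraries (CT and VPA) and 16291 genes in 3 libraries (NPC). Of the gene identifiers 98.1% to 100.0% matched the GENCODE M21 annotation of GRCm38/mm10, which gave coordinates and gene types. All per-sample columns were used, and 4 of 48 labelled samples, replicate 3 of both genotypes at P7 and P14, were not analysed here.

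FPKM times the merged exon length came in whole read steps, within 0.05 reads, for 97.1% to 99.2% of the low values in 23 libraries, and for 13.3% to 19.4% in the other 21. The second set held all P21 libraries, replicate 3 at P1 and P45, VPA 3 and NPC C3, whose depth is unknown, and the labels do not say why. The FPKM of a library summed to 238106 to 258920 in the 16 whole-read libraries of the age series and to 364520 to 381834 in its other 4. The sums were 344637 to 421747 at P21, 66557 to 72783 in the 5 whole-read CT and VPA libraries, and 150149 in VPA 3.

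Values were analysed as log2 of FPKM with 1 added, for genes with a mean of at least 0.5 FPKM over the libraries of a table, which left 19733, 16420 and 11264 genes. Each table was fitted separately with limma 3.58.1 in R 4.3.3, with 1 mean per group and moderated variances with a trend and robust estimation (statmod 1.5.0). The Benjamini-Hochberg adjusted p had to be under 0.05. There were 15 comparisons: mG-cKO against Ctrl at each age, P45 against P1 in Ctrl, the difference of the mG-cKO effects between P45 and P1, mG-cKD against Ctrl, mG-cKO against mG-cKD, RTI against none in each genotype, each RTI group against Ctrl, the difference of the RTI effects, and VPA against CT. The NPC libraries had no comparison. Tables were prepared and plotted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

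A set of 33 gene lists was tested with camera at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. The lists covered complement, homeostatic and reactive microglia, interferon-stimulated genes, nucleic acid sensors, antigen presentation, inflammatory cytokines, astrocytes, reactive astrocytes, oligodendrocytes and their precursors, neural progenitors, excitatory and inhibitory neurons, synapses, autism risk and immediate early genes. They also covered retroelement silencing, germline genes, retrovirus-derived host genes, histone deacetylases, vascular, choroid plexus, meningeal, erythroid and leukocyte genes, other brain regions, sex-linked, mitochondrially encoded and ribosomal protein genes, replication-dependent histones, zinc finger genes and clustered protocadherins. Of 182 list calls over all comparisons 14 held with an estimated correlation.

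Replicate numbers were read as pairs where the correlation across genes between libraries of the same number, after group means were removed, was above 0.1 for each of 3 numbers. This held for mG-cKO against Ctrl at P1 (0.782, 0.71 and 0.942), P45 (0.871, 0.887 and 0.969) and P21 (0.157, 0.125 and 0.698), for mG-cKO against mG-cKD (0.522, 0.331 and 0.693) and for P45 against P1 in Ctrl (0.584, 0.556 and 0.665). At P1 and P45 the third number is also the one without whole read steps, so there the rule cannot tell pairs from that difference. Libraries correlated best with their own number for 2 of 3 numbers at P1, at P45 and for age in Ctrl. At P21 this held for 1 of 3 against Ctrl and 3 of 3 against mG-cKD. The labels do not state a pairing, so results without the block are reported. The block is set beside C4b and the counts over all genes where the numbers met the rule and it changed them. Counts of list members are given without it.

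Genes named in the text followed a rule: C4b in every comparison, then the 8 largest increases and decreases among genes past the threshold whose groups did not overlap, without symbols of the form Gm and a number or ending in Rik and without genes not coding for protein where the table gives the type. From each list with a call came the 2 called members with the smallest adjusted p. Where fewer than 5 genes passed, the 5 with the smallest p were named, and some genes the rule names are not reported here. Further list members were added after their values were seen: Stag3 aside, these were Ifit3, Ddx4 and Sycp3 at the ages where they complete a list, Pcdha11, Pcdhb6 and Pcdhga6. The groups, comparisons, lists, naming rule and main alternatives were chosen before the data were examined.

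The alternatives were a pseudocount of 0.1, no filter on low values, libraries scaled to a common median ratio, a fit of the compared groups alone, the replicate block, variances without trend and robust estimation, and each library left out in turn. Chosen after seeing the data were the whole read steps as a covariate, the whole-read libraries alone, list medians within whole-read libraries and within replicate 3, the untreated P21 groups alone with the block, and leaving out mG-cKD RTI 1 and mG-cKO 2 together.

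The fit was tested on simulated data with the same designs, with noise independent between libraries and genes. Changes were put only in genes with a mean log2 level above 1. It recovered 25.4% to 82.1% of changes of 1 on the log2 scale and 59.7% to 97.0% of changes of 2, and 2.14% to 9.93% of calls were false. Of 15 simulated lists of 30 genes shifted by 0.5 all were called, and 0 of the unshifted lists. The simulated libraries held no structure shared between libraries or genes, so these shares need not hold for the real data. Correlations of 2 sets of differences that share libraries were set against 100 simulations without effects.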

Results

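Gene expression was measured by RNA sequencing of mouse cortex, and the values are FPKM, fragments scaled to gene length and to the mapped fragments of the library. The labels list 48 samples, of which 44 had a column of values and were analysed here. The age series held Ctrl and mG-cKO cortex at P1 and P45 with 3 libraries per group, and at P7 and P14 with 2 libraries per group. Replicate 3 of both genotypes at P7 and P14 was not analysed here. The P21 table held 3 libraries each of Ctrl, mG-cKD, mG-cKD given RTI, mG-cKO and mG-cKO given RTI. A separate table held 3 libraries labelled CT and 3 labelled VPA at P1, and another held 3 libraries titled NPC. The sample titles call Ctrl WT, mG-cKD Het and mG-cKO MT. The labels do not spell out mG, RTI, VPA or NPC, and they do not name the gene altered in mG-cKD and mG-cKO, so its loss could not be checked.

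The values of 23 libraries came in whole read steps and implied depths of 13.54 to 30.95, in units of 1e+06 reads. The depth of the other 21 libraries is unknown, among them all P21 libraries and replicate 3 at P1 and P45. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples. Differences are given as log2 differences of FPKM with 1 added, ± the limma standard error, which understates changes of genes with low FPKM. Group levels are means ± SD in FPKM.

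C4b encodes complement component C4, which tags surfaces for removal by phagocytes, and the series title names it as the gene raised by hybrids of RNA and DNA that derive from endogenous retroviruses. C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882, minus strand, GRCm38/mm10) was higher in mG-cKO than in Ctrl at P7, P14, P21 and P45. At P7 it was at 9.38 ± 1.65 FPKM in mG-cKO (n = 2) and 1.45 ± 0.03 in Ctrl (n = 2), a log2 difference of 2.07 ± 0.19 (adjusted p = 9.5e-05). At P14 the levels were 14.9 ± 3.22 (n = 2) and 1.76 ± 0.20 (n = 2), a difference of 2.52 ± 0.19 (adjusted p = 1.4e-05). At P21 they were 22.9 ± 3.37 (n = 3) and 1.89 ± 0.12 (n = 3), a difference of 3.04 ± 0.27 (adjusted p = 1.8e-05). At P45 they were 24.02 ± 5.82 (n = 3) and 2.70 ± 0.33 (n = 3), a difference of 2.74 ± 0.15 (adjusted p = 4.5e-07). At P1 C4b was at 1.26 ± 0.09 in mG-cKO and 0.458 ± 0.086 in Ctrl (n = 3 each), and all mG-cKO libraries lay above all Ctrl libraries, but the difference of 0.64 ± 0.15 did not pass (adjusted p = 0.465). With the replicate numbers as a block it passed at P1 (adjusted p = 0.0242), and with a pseudocount of 0.1 as well (adjusted p = 0.0068). The related gene C4a, 65 kb away, did not pass at any age and had a log2 difference of 0.55 ± 0.16 at P21 (adjusted p = 0.119). Within the whole-read libraries the C4b difference was 0.71 at P1 and 2.62 at P45, and within the replicate 3 pairs it was 0.48 and 2.97.

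**Figure D1:**
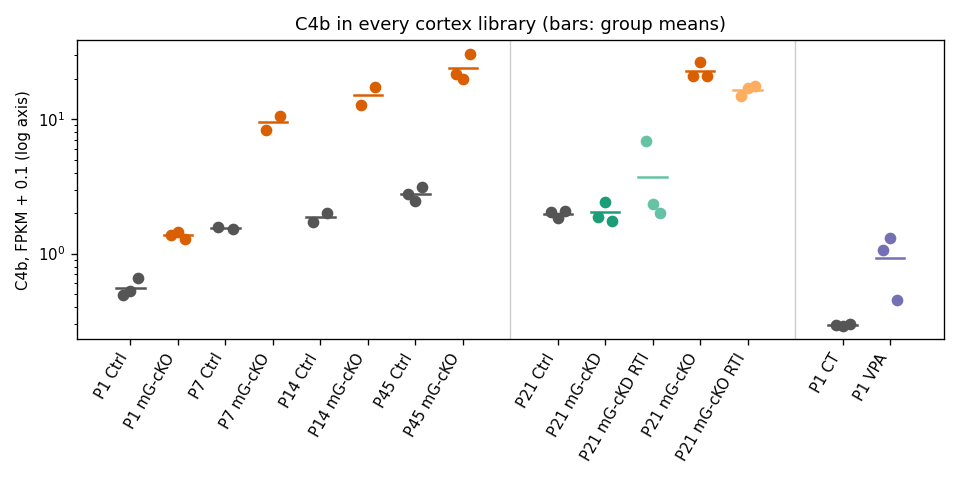
C4b level in each cortex library on a log axis (FPKM with 0.1 added), with 1 point per library, bars at the group means and vertical lines between tables that were tested separately. Every mG-cKO library from P7 on, 8.21 FPKM or more, lay above every Ctrl library of its table.

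At P1, shortly after birth, few genes differed between mG-cKO and Ctrl cortex. Prm1, which encodes a protamine that packs DNA in sperm (chromosome 16, 10796326 to 10805839), was at 7.73 ± 2.19 FPKM in mG-cKO (n = 3) and 0.367 ± 0.415 in Ctrl (n = 3), a log2 difference of 2.69 ± 0.20 (adjusted p = 1.3e-05). Tcfl5, a transcription factor of spermatocytes (chromosome 2, 180621956 to 180642708), rose by 2.28 ± 0.19 from 0.880 ± 0.155 FPKM in Ctrl (adjusted p = 4.2e-05). Mnd1, a factor of meiotic recombination (chromosome 3, 84087933 to 84155786), rose by 2.24 ± 0.20 from 0.622 ± 0.174 FPKM (adjusted p = 6.2e-05). Hamp2, a hepcidin gene, was listed at 0 in all Ctrl libraries and at 2.45 ± 0.95 FPKM in mG-cKO (adjusted p = 7.5e-04). Gramd1c (chromosome 16, 43980350 to 44063345) rose by 1.61 ± 0.11 (adjusted p = 3.5e-06), Pcdhgb4 by 2.18 ± 0.38 (0.0406), Dennd1c by 1.005 ± 0.17 (0.0387) and Pcdha11 (ENSMUSG00000007440) by 0.93 ± 0.16 (0.0438), while a second entry of that symbol (ENSMUSG00000102206) had 0.17 ± 0.71 (adjusted p = 1). Genes that fell included Neurog2, a proneural factor of cortical progenitors (-0.78 ± 0.13, 2.76 ± 0.43 FPKM in Ctrl) and Gm27032, a long noncoding RNA outside the rule for named genes and chosen after its values were seen (-0.60 ± 0.10).

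Of the 57 measured clustered protocadherins, which encode neuronal cell surface identity proteins, 2 rose at P1 (Pcdhgb4 and Pcdha11), or 5 adjusted over the list alone. The protocadherin list as a set was higher, with a median of 0.27 (adjusted p = 4.2e-22, and adjusted p = 0.0491 with an estimated correlation). Of 10 measured germline genes, Stag3, a cohesin subunit of meiosis, rose by 0.81 ± 0.13, with 3 adjusted over the list alone, and the list was higher (median 0.19, adjusted p = 1.3e-08, and adjusted p = 0.0013 with an estimated correlation). Of 19 neural progenitor genes Neurog2 fell, 1 adjusted over the list alone, and the list was lower (median -0.22, adjusted p = 3.1e-16, and adjusted p = 0.0089 with an estimated correlation). The oligodendrocyte list had no member past the threshold at P1 or P7 in limma, and its members showed median differences of 0.00 within the whole-read libraries and 0.03 within the replicate 3 pair at P1.

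In all, 28 of 19733 genes passed at P1, 25 higher and 3 lower, and 343 had an unadjusted p under 0.05. With the replicate numbers as a block 181 passed, 101 higher and 80 lower. Xist ranged from 0.02 to 129 FPKM in the Ctrl libraries and from 0.04 to 120 in the mG-cKO libraries of P1. Its means were 68.7 and 40.1, so the sexes were not balanced between these groups. The count fell to 13 without Ctrl 1, 13 without mG-cKO 1, 17 without Ctrl 2 and 18 without mG-cKO 2. The calls of Pcdhgb4, Dennd1c, Pcdha11, Neurog2 and Stag3 all ended without Ctrl 1 (adjusted p 0.141 to 0.314) and without mG-cKO 1 (0.0776 to 0.152). Those of Dennd1c, Pcdha11 and Neurog2 ended without any of the 6 libraries, and that of Pcdhgb4 also without Ctrl 2 (0.212). That of Stag3 ended also without Ctrl 2 (0.102), mG-cKO 2 (0.0681) or mG-cKO 3 (0.117). Scaling the libraries to a common median ended the calls of Neurog2 (0.106) and Pcdha11 (0.139), and a pseudocount of 0.1 those of Neurog2 (adjusted p = 1), Dennd1c (0.0903), Stag3 (0.0773) and Pcdha11 (0.062).

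At P7 the increases again included Prm1, Tcfl5, Hamp2, Mnd1 and Gramd1c, and C4b joined them. Prm1 was at 11.9 ± 0.29 FPKM in mG-cKO (n = 2) and 0.430 ± 0.0005 in Ctrl (n = 2), a log2 difference of 3.17 ± 0.25 (adjusted p = 2.6e-05). Tcfl5 rose by 2.62 ± 0.23 (adjusted p = 9.5e-05), Hamp2 by 2.16 ± 0.24 (7.8e-04), Mnd1 by 1.75 ± 0.24 (0.0062) and Gramd1c by 1.72 ± 0.13 (2.6e-05). Pcdhga8, a gamma protocadherin (chromosome 18, 37725706 to 37841873), rose by 1.98 ± 0.24 from 2.56 ± 0.35 FPKM in Ctrl (adjusted p = 0.0014). Gpnmb, a glycoprotein of phagocytic microglia, rose by 1.51 ± 0.22 from 0.327 ± 0.028 FPKM (adjusted p = 0.0078). The reactive microglia list was higher as a set (17 measured, 1 higher, 3 adjusted over the list alone, median 0.34, adjusted p = 5.2e-20, and adjusted p = 0.0142 with an estimated correlation). The homeostatic microglia list had a median of 0.24 with no member called and 2 adjusted over the list alone (adjusted p = 3.9e-13, and adjusted p = 0.0669 with an estimated correlation).

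The protocadherin list was higher at P7, with 3 of 57 called (Pcdha1, Pcdhga8 and Pcdha11), 10 adjusted over the list alone and a median of 0.34 (adjusted p = 5.4e-28, and adjusted p = 0.0219 with an estimated correlation). The germline list was higher, with Stag3 called (1.03 ± 0.15), 1 of 10 adjusted over the list alone and a median of 0.19 (adjusted p = 5.5e-05, and adjusted p = 0.0142 with an estimated correlation). Across all genes 32 of 19733 passed, 31 higher and 1 lower, and 322 had an unadjusted p under 0.05. With whole-read libraries alone 403 passed, 245 higher and 158 lower. The gene that fell was G530011O06Rik (-1.08 ± 0.20), which lay outside the rule for named genes and was chosen after its values were seen. Of the 31 genes higher at P7, 17 were among the 25 higher at P1, where 0.0393 would be shared by chance if calls were independent. The ages of this table share an estimate of each gene's spread, so such chance values set no fair bound. Each group had 2 libraries, and leaving out any of the 4, where the spread of that group comes from the other groups alone, gave 15 to 17 genes (17 without Ctrl 1, 15 without Ctrl 2, 16 without mG-cKO 1, 15 without mG-cKO 2). The calls of Gpnmb and Stag3 ended without any of the 4 (adjusted p 0.0789 to 0.252), that of Gpnmb also with a pseudocount of 0.1 (0.084), and that of Mnd1 without Ctrl 2 (0.126) or mG-cKO 2 (0.144).

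At P14 genes of myelin fell in mG-cKO cortex and class II antigen presentation genes rose. Mal, a proteolipid of compact myelin (chromosome 2, 127633226 to 127656695), was at 2.77 ± 0.44 FPKM in mG-cKO (n = 2) and 22.5 ± 3.002 in Ctrl (n = 2), a log2 difference of -2.64 ± 0.18 (adjusted p = 5.6e-06). Opalin (-1.76), Ermn (-1.75), Gsn (-1.73), Cldn11 (-1.71) and Ugt8a (-1.62) fell on the log2 scale, all with adjusted p of 0.0018 or less. Of the 15 measured oligodendrocyte genes 6 fell, or 12 adjusted over the list alone, and the median was -1.71 (adjusted p = 8.7e-62, and adjusted p = 3.5e-04 with an estimated correlation). H2-Ab1, a class II chain (chromosome 17, 34257689 to 34269419), rose by 3.58 ± 0.39 from 0.466 ± 0.212 to 16.4 ± 1.07 FPKM (adjusted p = 3.7e-04). H2-Eb1 rose by 2.11 ± 0.20 and H2-Aa by 1.998 ± 0.25. These were the 3 of 13 antigen presentation genes that passed, with 4 adjusted over the list alone, and the call of the list was lost with an estimated correlation (median 0.25, adjusted p = 3.1e-14, and adjusted p = 0.231 with an estimated correlation).

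Tcfl5 (2.83 ± 0.23), Prm1 (2.76 ± 0.25), Pcdhga8 (2.24 ± 0.24) and Gramd1c (1.94 ± 0.13) were also higher at P14, all with adjusted p of 2.6e-04 or less. Of the protocadherins 4 of 57 rose (Pcdha1, Pcdhga8, Pcdhb6 and Pcdhga6), with 9 adjusted over the list alone (median 0.20, adjusted p = 2.8e-14, and adjusted p = 0.231 with an estimated correlation). The choroid plexus list, whose Ttr was at 241 FPKM in Ctrl 2 of P7 and of P14 against 4.93 in the other Ctrl library of P14, had a median of -0.44 with no member called (adjusted p = 0.0012, and adjusted p = 0.246 with an estimated correlation). Across all genes 68 passed, 53 higher and 15 lower, and 553 had an unadjusted p under 0.05. The balance turned to 77 higher and 84 lower in a fit of the P14 groups alone and to 432 and 734 with whole-read libraries alone. The genes higher at P14 included 25 of the 31 higher at P7, where 0.0833 would be shared by chance if calls were independent, again no fair bound. Leaving out any of the 4 libraries, with the spread again taken from other groups, gave 36 to 42 genes (38 without Ctrl 1, 39 without Ctrl 2, 42 without mG-cKO 1, 36 without mG-cKO 2). The call of Cldn11 ended without mG-cKO 2 (adjusted p = 0.0503). Xist was at 48.6 FPKM or more and Ddx3y at 0 in all P14 libraries analysed.

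At P45 the oligodendrocyte list was lower in mG-cKO. Of the genes higher earlier, 18 of the 25 at P1, 28 of the 31 at P7 and 46 of the 53 at P14 were called higher again. Independent calls would share 0.174, 0.215 and 0.368 by chance, but these ages share an estimate of each gene's spread, so these values set no fair bound. Mal was at 10.5 ± 1.82 FPKM in mG-cKO (n = 3) and 54.1 ± 5.67 in Ctrl (n = 3), a log2 difference of -2.26 ± 0.15 (adjusted p = 1.5e-06). Mobp (-2.45), Mag (-2.19), Cldn11 (-2.15), Ermn (-2.15), Fa2h (-2.08) and Mog (-2.04) fell on the log2 scale, with adjusted p from 5.8e-06 for Ermn to 0.029 for Mog. Of 15 oligodendrocyte genes 13 fell, or 14 adjusted over the list alone, with a median of -2.08 (adjusted p = 5.4e-65, and adjusted p = 2.7e-04 with an estimated correlation). The median was -2.18 within the whole-read libraries and -1.91 within the replicate 3 pair. Of 11 oligodendrocyte precursor genes Sox10 (-1.24 ± 0.27) and Bcas1 (-1.72 ± 0.37) fell, with 3 adjusted over the list alone (median -0.28, adjusted p = 1.0e-08, and adjusted p = 0.274 with an estimated correlation).

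Bglap3, an osteocalcin family gene (chromosome 3, 88368616 to 88372743), was the largest increase among coding genes at P45, from 0.666 ± 0.430 to 19.6 ± 13.3 FPKM (3.48 ± 0.42, adjusted p = 3.4e-04). Cox6a2, the muscle form of a cytochrome c oxidase subunit, rose by 3.26 ± 0.44, Mnd1 by 3.03 ± 0.20, Tcfl5 by 2.85 ± 0.19, Gramd1c by 2.70 ± 0.11, Pcdhga8 by 2.52 ± 0.19 and Prm1 by 2.25 ± 0.20. Of 57 protocadherins 10 rose, or 21 adjusted over the list alone, with a median of 0.54 (adjusted p = 1.6e-25, and adjusted p = 0.0317 with an estimated correlation). Alpha and gamma protocadherin genes share the last exons of their cluster, so their reads are hard to assign to single members. Of 10 germline genes Stag3 (1.62 ± 0.13) and Ddx4, an RNA helicase of germ cells (1.05 ± 0.17), rose, with 4 adjusted over the list alone (median 0.22, adjusted p = 8.6e-07, and adjusted p = 0.0024 with an estimated correlation). Of 24 interferon-stimulated genes Ifit1, Ifit3 and Ifit3b rose by 0.87, 0.93 and 0.71, with 10 adjusted over the list alone (median 0.43, adjusted p = 2.1e-15, and adjusted p = 0.0677 with an estimated correlation). Ifit3 and Ifit3b are close copies, so their separate values are uncertain. Cd74, the invariant chain of class II, rose by 1.20 ± 0.18, the only one of 13 antigen presentation genes, with 4 adjusted over the list alone (median 0.45, adjusted p = 2.9e-09, and adjusted p = 0.274 with an estimated correlation). Of the ribosomal protein list 3 of 81 rose, 6 adjusted over the list alone, with a median of 0.58 (adjusted p = 2.5e-18, and adjusted p = 0.29 with an estimated correlation).

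Across all genes 228 of 19733 passed at P45, 137 higher and 91 lower, and 1152 had an unadjusted p under 0.05. With the replicate block 2740 passed. Replicate 3 of both genotypes lacks whole read steps, but replicates 1 and 2 were the ones unlike P1. They held 19052 to 19137 genes at 1 FPKM or more, against 14088 and 14426 in replicate 3 of P45. Replicates 1 and 2 of P1, which also come in whole read steps, held 14435 to 14501. That argues against read steps as the whole source of the difference within P45. Fitted on the 6 P45 libraries alone without a block, 0 genes passed in limma. Rn7sk, a noncoding RNA without a poly(A) tail, was at 18350 to 21130 FPKM in replicates 1 and 2 of both genotypes and at 0.63 and 72.8 FPKM in replicate 3. Single libraries ended the calls of Mobp (without mG-cKO 1, adjusted p = 0.127, mG-cKO 2, 0.129, or Ctrl 3, 0.0669), Mag (without mG-cKO 1, 0.0939, or mG-cKO 2, 0.0929) and Mog (without Ctrl 1, 0.168, Ctrl 2, 0.0776, mG-cKO 1, 0.129, mG-cKO 2, 0.101, or mG-cKO 3, 0.0601). They also ended those of Sox10 and Bcas1 (each without Ctrl 1, mG-cKO 1, mG-cKO 2 or Ctrl 3, 0.0916 to 0.209), Ifit3b (without mG-cKO 1, 0.0588) and Ifit1 (without Ctrl 1, 0.0597, or mG-cKO 1, 0.105). With a pseudocount of 0.1 the calls of Ifit3b, Ifit1 and Bcas1 ended (adjusted p = 0.498, 0.209 and 0.0729), and with libraries scaled to a common median that of Mog (0.0544).

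**Figure D2:**
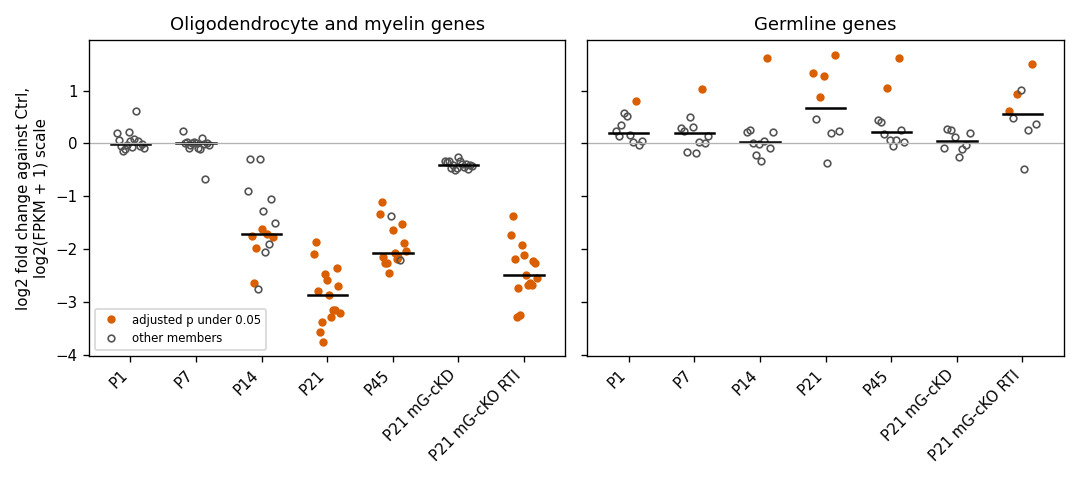
Log2 difference from Ctrl (vertical axis) of each measured member of the oligodendrocyte and germline lists, for mG-cKO at each age and for mG-cKD and RTI-treated mG-cKO at P21, with filled points for members past the threshold and bars at the medians. The oligodendrocyte medians were -1.71 at P14, -2.86 at P21 and -2.08 at P45, and -0.40 in mG-cKD.

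Ctrl cortex at P45 was compared with Ctrl cortex at P1. Rn7sk was at 1.14 to 5.14 FPKM in Ctrl at P1, at 20520 and 21130 in Ctrl 1 and 2 of P45 and at 0.63 in Ctrl 3, and genes at 1 FPKM or more numbered 14311 to 14501 at P1 and 19088, 19137 and 14088 at P45, so Ctrl 1 and 2 of P45 stood apart from all others here. Myelin genes rose, with Mobp from 0.029 ± 0.032 to 127 ± 92.1 FPKM (n = 3 each, 6.72 ± 0.49, adjusted p = 1.1e-07), Mbp by 5.34 ± 0.78, Mal by 5.16 ± 0.15 and Mag by 4.94 ± 0.41. Arc, an activity-induced gene, rose by 4.69 ± 0.39, Pvalb, a marker of fast-spiking interneurons, by 4.47 ± 0.20, and Fam107a by 4.42 ± 0.27. Among the largest decreases were Cd24a from 318 ± 71.0 to 2.56 ± 1.21 FPKM (-6.51 ± 0.23, adjusted p = 9.3e-11), Dpysl3 (-5.45 ± 0.15), Igfbpl1 (-5.32 ± 0.16), St8sia2 (-5.30 ± 0.09), Trim67 (-5.27 ± 0.10), Tubb2b (-5.13 ± 0.40), Draxin (-4.76 ± 0.09) and Dpysl5 (-4.72 ± 0.26). C4b rose by 1.34 ± 0.15 (adjusted p = 9.2e-06).

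All 15 list calls of this comparison were lost with an estimated correlation, the lowest for neural progenitors (adjusted p = 0.108 with an estimated correlation) and oligodendrocytes (adjusted p = 0.11 with an estimated correlation). Lists with more members higher than lower with age in Ctrl (adjusted p from 0.11 to 0.391 with an estimated correlation) were those of oligodendrocytes (13 of 15 called, 15 adjusted over the list alone, median 3.23), astrocytes (11 of 16, 11 alone, 1.31), homeostatic microglia (13 of 18, 15 alone, 1.29), synapses (19 of 36, 21 alone, 0.90) and immediate early genes (14 of 16, 14 alone, 1.93). Lists with more members lower (adjusted p from 0.108 to 0.427 with an estimated correlation) were those of neural progenitors (15 of 19 lower and 1 higher, 16 adjusted over the list alone, median -1.35), ribosomal proteins (52 of 81 lower and 1 higher, 64 alone, -1.51), retroelement silencing factors (18 of 38 lower and 1 higher, 20 alone, -0.58) and meningeal fibroblasts (8 of 11 lower, 9 alone, -0.88). Zinc finger genes had 110 of 360 lower and 26 higher (137 adjusted over the list alone, median -0.23), and replication-dependent histones 12 of 44 higher and 2 lower (33 alone, 1.61), with adjusted p = 0.314 and 0.808 with an estimated correlation. The histone median was 2.41 within the whole-read libraries and 0.00 within the replicate 3 pair, that of ribosomal proteins -1.70 and -1.12, and that of oligodendrocytes 3.10 and 3.52. Further lists with called members were those of autism risk genes (4 higher and 4 lower of 39, 8 adjusted over the list alone, median -0.15), nucleic acid sensors (4 and 3 of 17, 7 alone, -0.23), inflammatory cytokines (0 and 2 of 13, 2 alone, 0.02), histone deacetylases (1 and 4 of 11, 6 alone, -0.42), vascular genes (5 and 6 of 16, 11 alone, -0.07), inhibitory neuron genes (4 and 4 of 16, 8 alone, -0.43) and excitatory neuron genes (3 and 9 of 15, 12 alone, -0.57). Erythroid genes had 1 of 5 higher (1 alone, 0.87), peripheral leukocyte genes 3 of 4 lower (3 alone, -1.17) and mitochondrially encoded genes 3 of 36 higher (2 alone, 0.45). Genes of other brain regions had 1 of 15 higher and 5 lower (7 alone, 0.17), retrovirus-derived host genes 1 of 12 higher and 5 lower (7 alone, -0.47), and complement genes 5 of 17 higher and 2 lower (7 alone, 0.27). Of 5 sex-linked genes, 3 adjusted over the list alone, Uty rose by 1.86 ± 0.45, where Ddx3y was read in every P45 library and Xist in Ctrl 1 and Ctrl 3 of P1. In all, 7221 of 19733 genes passed, 3388 higher and 3833 lower. For Ctrl 1 and 2 of P45 this count mixes age with whatever sets those libraries apart. The balance turned to 7153 higher and 6732 lower with the replicate block (13885 in all) and to 4059 and 3554 with libraries scaled to a common median.

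The test of the difference between ages asked which mG-cKO effects were larger or smaller at P45 than at P1. Xist reached 129 FPKM in Ctrl and 120 in mG-cKO at P1, while Ddx3y was at 7.11 or more in every P45 library. Sex thus differed between the ages, and its part in the interaction was not tested. Myelin genes had a lower mG-cKO effect at P45 than at P1, with Cldn11 at an interaction of -2.77 ± 0.26 (adjusted p = 3.2e-04), Mal -2.12 ± 0.21, Ermn -2.09 ± 0.23, Opalin -1.87 ± 0.25, Tmem88b -1.87 ± 0.20 and Hapln2 -1.81 ± 0.27. At P1 Mal was at 0.534 ± 0.138 FPKM in Ctrl and 0.394 ± 0.171 in mG-cKO (n = 3 each). A level this low in Ctrl leaves little room for a fall at P1 on this scale. C4b had an interaction of 2.10 ± 0.22 (adjusted p = 4.9e-04), Tmc1, a channel subunit of hair cells, 1.93 ± 0.20, Fgf21 1.76 ± 0.32, Pcdha1 1.59 ± 0.19, Fabp7 1.56 ± 0.26, Pcdhga8 1.56 ± 0.27, Stc2 1.35 ± 0.15 and P2rx7 1.27 ± 0.19. The oligodendrocyte list was lower (8 of 15 called, 13 adjusted over the list alone, median -2.01, adjusted p = 2.0e-71, and adjusted p = 1.7e-04 with an estimated correlation). The other 12 list calls were lost with an estimated correlation, among them interferon-stimulated genes (median 0.36, adjusted p = 0.239 with an estimated correlation).

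In all, 71 of 19733 genes passed the interaction, 34 higher and 37 lower, 576 had an unadjusted p under 0.05, and 1038 passed with the replicate block, 544 higher and 494 lower. The count was 39 without Ctrl 1 of P1, 41 without Ctrl 2 of P1, 45 without mG-cKO 1 of P1, 44 without mG-cKO 3 of P1, 45 without Ctrl 1 of P45 and 46 without mG-cKO 1 of P45. The calls of Fgf21, Fabp7 and Pcdhga8 ended without Ctrl 1 of P1 (adjusted p 0.0554 to 0.0889), Ctrl 2 of P1 (0.0646 to 0.0847) and mG-cKO 2 of P1 (0.0514 to 0.0809), and each without 3 or more of the other libraries (up to 0.0969). With a pseudocount of 0.1 the calls of Fgf21 (adjusted p = 0.18), Pcdhga8 (0.0754), Ermn (0.0723), Opalin (0.0862) and Hapln2 (0.0581) ended, and with libraries scaled to a common median that of Pcdhga8 (0.0584).

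At P21 mG-cKD cortex showed no gene past the threshold against Ctrl. C4b was at 1.93 ± 0.36 FPKM in mG-cKD and 1.89 ± 0.12 in Ctrl (n = 3 each), a log2 difference of 0.01 ± 0.27. Prm1 was at 5.81, 3.13 and 7.26 FPKM in the mG-cKD libraries and at 0.27 or less in Ctrl. The smallest p-values belonged to Gm22121 (1.03 ± 0.17), Gm13301 (-0.94 ± 0.16), Gm3893 (-0.68 ± 0.12), Gm13302 (-0.72 ± 0.15) and Gm42669 (0.56 ± 0.13), with adjusted p from 0.312 to 1. The 15 oligodendrocyte genes had a median of -0.40 with 0 called and 0 adjusted over the list alone (adjusted p = 1.4e-08, and adjusted p = 0.332 with an estimated correlation). Immediate early genes had a median of -0.53 with 0 of 16 called and 5 adjusted over the list alone (adjusted p = 3.4e-18, and adjusted p = 0.0885 with an estimated correlation). Of 16420 genes tested with limma 0 passed, and 231 had an unadjusted p under 0.05. Leaving out Ctrl 2 gave 1 gene. Xist was at 26.9 and 27.1 FPKM in mG-cKD 1 and 3 and at 0.04 or less in mG-cKD 2 and in all Ctrl and mG-cKO libraries without RTI, which all held Ddx3y.

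At P21 mG-cKO cortex showed the largest genotype effects of the P21 groups without RTI. Mobp was at 33.4 ± 4.85 FPKM in mG-cKO and 460 ± 61.2 in Ctrl (n = 3 each), a log2 difference of -3.75 ± 0.35 (adjusted p = 2.9e-05). Mal (-3.56), Mag (-3.28), Mog (-3.21), Mbp (-3.16), Cldn11 (-3.15) and Fa2h (-2.86) fell on the log2 scale, all with adjusted p of 1.6e-04 or less. All 15 oligodendrocyte genes fell, and all 15 adjusted over the list alone, with a median of -2.86 (adjusted p = 5.3e-54, and adjusted p = 0.0051 with an estimated correlation). Of 11 oligodendrocyte precursor genes Sox10 (-1.33 ± 0.25) and Bcas1 (-1.47 ± 0.20) fell, with 4 adjusted over the list alone (median -0.29, adjusted p = 1.1e-05, and adjusted p = 0.221 with an estimated correlation). Pdgfra and the other precursor markers did not pass. Gfap, a marker of reactive astrocytes, rose by 1.24 ± 0.21 from 50.7 ± 6.62 FPKM (adjusted p = 0.0032) and Aspg by 1.36 ± 0.21, the 2 of 21 reactive astrocyte genes that passed, both also adjusted over the list alone (median 0.31, adjusted p = 4.9e-04, and adjusted p = 0.221 with an estimated correlation).

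Bglap3 rose by 3.78 ± 0.41 at P21, Pcdhga8 by 3.64 ± 0.34, Tcfl5 by 3.59 ± 0.17, Gramd1c by 2.87 ± 0.27, Prm1 by 2.87 ± 0.57 and Mnd1 by 2.67 ± 0.43. Stk19-ps1, a pseudogene beside C4b (chromosome 17, 34744753 to 34747154), was listed at 0 in all Ctrl libraries and at 9.08 ± 1.02 FPKM in mG-cKO (adjusted p = 1.1e-07). Of 56 protocadherins 16 rose, or 27 adjusted over the list alone (median 0.42, adjusted p = 6.9e-17, and adjusted p = 0.0876 with an estimated correlation). Of 8 germline genes Stag3 (1.68), Taf7l (1.34), Ddx4 (1.28) and Sycp3 (0.89) rose, with 5 adjusted over the list alone (median 0.68, adjusted p = 1.2e-06, and adjusted p = 0.0754 with an estimated correlation). Of 29 interferon-stimulated genes 3 rose, among them Oasl2 (1.52 ± 0.32) and Ifi27l2a (1.25 ± 0.21), or 14 adjusted over the list alone (median 0.69, adjusted p = 5.4e-12, and adjusted p = 0.221 with an estimated correlation). Of 15 antigen presentation genes Cd74 (1.45 ± 0.19) and H2-Eb1 (0.81 ± 0.19) rose, or 8 adjusted over the list alone (median 0.81, adjusted p = 2.6e-07, and adjusted p = 0.176 with an estimated correlation). Homeostatic microglia genes had 0 of 18 called, 0 adjusted over the list alone and a median of -0.15 (adjusted p = 0.0069, and adjusted p = 0.492 with an estimated correlation).

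Across all genes 360 of 16420 passed at P21, 222 higher and 138 lower, and 1710 had an unadjusted p under 0.05. With the replicate block 359 passed, and with the untreated groups alone and the block 587. Of the genes tested at both ages, 83 were higher at P21 and P45 and 62 were lower at both, where 1.56 and 0.70 would be shared by chance. Single libraries ended the calls of Prm1 (without Ctrl 1, adjusted p = 0.0665, Ctrl 3, 0.0774, mG-cKO 2, 0.0539, or mG-cKO 3, 0.0616), Oasl2 (without any of the Ctrl libraries or mG-cKO 2, 0.0558 to 0.107), H2-Eb1 (without any but Ctrl 3, 0.0674 to 0.192) and Sox10 (without mG-cKO 2, 0.0502). With libraries scaled to a common median the call of H2-Eb1 ended (0.0539).

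**Figure D3:**
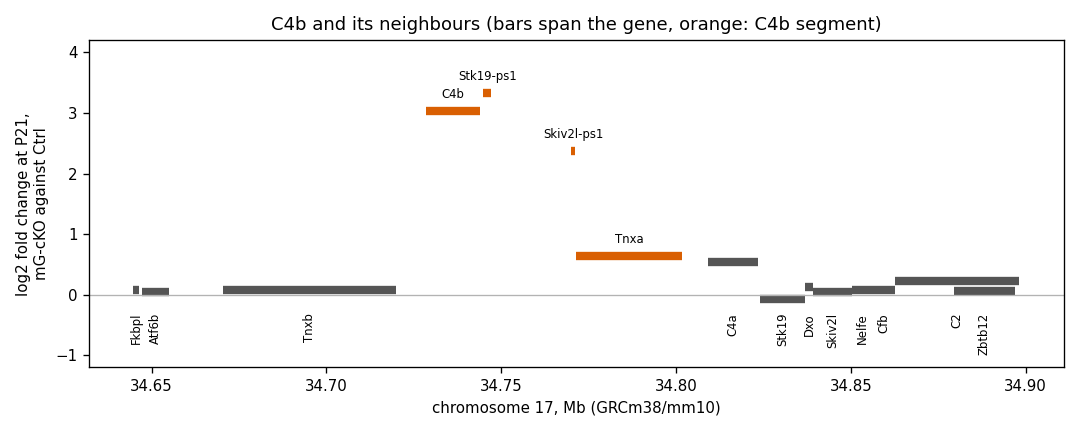
Log2 difference between mG-cKO and Ctrl at P21 (vertical axis) of the genes around C4b on chromosome 17 (horizontal axis, Mb), each bar spanning the annotated gene. C4b, Stk19-ps1 and Skiv2l-ps1 lay at 3.04, 3.33 and 2.38, and C4a, Stk19, Skiv2l and Tnxb at 0.55 or less.

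Against mG-cKD at P21, mG-cKO showed much of the contrast seen against Ctrl. Prm1 was an exception, at 6.92 ± 0.81 FPKM in mG-cKO and 5.40 ± 2.09 in mG-cKD. C4b was at 22.9 ± 3.37 FPKM against 1.93 ± 0.36 in mG-cKD (n = 3 each), a log2 difference of 3.03 ± 0.27 (adjusted p = 2.6e-05). Bglap3 rose by 3.97 ± 0.41, Tcfl5 by 3.48 ± 0.17, Pcdhga8 by 3.42 ± 0.34, Stk19-ps1 by 3.09 ± 0.18, Gramd1c by 2.99 ± 0.27, Mnd1 by 2.76 ± 0.43 and Cox6a2 by 2.65 ± 0.44. Mobp (-3.24), Mal (-3.09), Mag (-2.90), Mog (-2.78), Mbp (-2.76), Cldn11 (-2.69) and Fa2h (-2.53) fell on the log2 scale. All 15 oligodendrocyte genes fell, and all 15 adjusted over the list alone (median -2.53, adjusted p = 1.9e-57, and adjusted p = 0.004 with an estimated correlation). Of 56 protocadherins 14 rose, or 24 adjusted over the list alone (median 0.42, adjusted p = 4.3e-19, and adjusted p = 0.0613 with an estimated correlation). In all, 251 genes passed, 174 higher and 77 lower, 259 passed with the replicate block, and 1213 had an unadjusted p under 0.05. Of the 222 genes higher against Ctrl, 165 were also higher against mG-cKD, and of the 138 lower against Ctrl 74 were also lower. Unrelated comparisons would share 2.35 and 0.647 by chance. Both comparisons use the mG-cKO libraries, so these chance values set no fair bound. The count was 156 without mG-cKD 2 and 162 without mG-cKO 2, and 379 with the untreated groups alone and the block.

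RTI was compared with no RTI within each genotype at P21. In mG-cKO, C4b was at 16.4 ± 1.42 FPKM with RTI and 22.9 ± 3.37 without (n = 3 each), a log2 difference of -0.45 ± 0.27 that did not pass (adjusted p = 0.962), where all RTI libraries lay below all others, as 9.85% of genes showed no overlap in this comparison and 10% would by chance. The gene that passed in mG-cKO was Gm20634 (chromosome 3, 96245554 to 96248509), which went from 2.33 ± 0.08 to 0.318 ± 0.216 FPKM (-1.35 ± 0.16, adjusted p = 0.0079). The next smallest p-values were those of Pycr1 (-0.72 ± 0.12), Pla2g5 (-1.01 ± 0.18), Olfr464 (-0.79 ± 0.14) and Pcdhga4 (-0.96 ± 0.19), with adjusted p from 0.285 to 0.646. The oligodendrocyte genes had a median of 0.49 with 0 of 15 called and 0 adjusted over the list alone (adjusted p = 3.5e-05, and adjusted p = 0.605 with an estimated correlation). In all, 1 of 16420 genes passed in limma and 649 had an unadjusted p under 0.05. The call of Gm20634 ended without mG-cKO 1 (adjusted p = 0.0699), without mG-cKO 3 (0.0674) and with a pseudocount of 0.1 (0.0558), and the count was 2 without mG-cKO 2 and 2 without mG-cKO RTI 2. Xist was at 27.1 and 36.4 FPKM in mG-cKO RTI 2 and 3 and at 0.04 or less in the other mG-cKO libraries of P21.

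In mG-cKD, C4b was at 6.75 FPKM in RTI 1 and at 2.25 and 1.90 in RTI 2 and 3, against 1.93 ± 0.36 without RTI (n = 3), a log2 difference of 0.52 ± 0.27 (adjusted p = 1). The smallest p-values were those of Gm22121 (-0.88 ± 0.17), Rab37 (0.62 ± 0.13), Arl4d (0.85 ± 0.19), Olfr464 (-0.64 ± 0.14) and Gm8034 (-0.82 ± 0.19), all with an adjusted p of 1. Prm1 was listed at 0 in mG-cKD RTI 1, against 6.75 and 6.33 FPKM in RTI 2 and 3, 3.13 to 7.26 in mG-cKD without RTI and 0.27 or less in Ctrl, which leaves the genotype label of RTI 1 in doubt. Without RTI 1, whose Rn7sk was at 44.9 FPKM against 6.36 and 6.56 in RTI 2 and 3, the C4b difference was 0.08. Erythroid genes had a median of 2.37 with 0 of 5 called and 0 adjusted over the list alone (adjusted p = 3.2e-05, and adjusted p = 0.371 with an estimated correlation), and Hbb-bs ranged from 8.30 to 194 FPKM among the mG-cKD libraries without RTI. In limma 0 genes passed and 353 had an unadjusted p under 0.05, and leaving out any library kept the count at 0. The test of the difference between the RTI effects in mG-cKO and mG-cKD gave 0 genes with limma and 245 at an unadjusted p under 0.05, with C4b at -0.97 ± 0.38 (adjusted p = 1). With 1 library left out this C4b value lay from -1.23 to -0.52. The smallest p-values of that test were those of Gm20634 (-1.23 ± 0.22), Gm28035 (-1.32 ± 0.32), Arid5a (-0.92 ± 0.24), Gm40123 (-0.70 ± 0.18) and H2-Q4 (-1.48 ± 0.39), and the count was 1 without mG-cKO 2. Immediate early genes had a median of -0.55 in it (0 of 16 called, 4 adjusted over the list alone, adjusted p = 7.3e-14, and adjusted p = 0.202 with an estimated correlation).

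RTI-treated mG-cKO cortex remained far from Ctrl. C4b was at 16.4 ± 1.42 against 1.89 ± 0.12 FPKM (n = 3 each), a log2 difference of 2.59 ± 0.27 (adjusted p = 1.3e-04). Tcfl5 rose by 3.52 ± 0.17, Pcdhgb8 by 3.03 ± 0.47, Prm1 by 2.94 ± 0.57, Bglap3 by 2.60 ± 0.41, Mnd1 by 2.54 ± 0.43 and H2-Ab1 by 2.44 ± 0.54, and Stk19-ps1, listed at 0 in Ctrl, was at 6.18 ± 1.35 FPKM. Mal (-3.27), Mobp (-3.25), Mbp (-2.68), Mag (-2.67), Cldn11 (-2.64), Mog (-2.54) and Fa2h (-2.48) fell on the log2 scale. All 15 oligodendrocyte genes fell, and all 15 adjusted over the list alone (median -2.48, adjusted p = 3.7e-38, and adjusted p = 0.0196 with an estimated correlation). Of 56 protocadherins 14 rose, or 25 adjusted over the list alone (median 0.31, adjusted p = 5.0e-11, and adjusted p = 0.197 with an estimated correlation). In all, 377 genes passed, 215 higher and 162 lower, and 2263 had an unadjusted p under 0.05. With libraries scaled to a common median the balance turned to 171 higher and 209 lower. The count was 220 without Ctrl 1, 189 without Ctrl 3, 177 without mG-cKO RTI 2, 188 without mG-cKO RTI 3 and 502 without mG-cKO RTI 1. The calls of Prm1 and H2-Ab1 ended without Ctrl 1 (adjusted p = 0.0566 and 0.105), Ctrl 3 (0.0778 and 0.0889), mG-cKO RTI 2 (0.0657 and 0.137) or mG-cKO RTI 3 (0.0658 and 0.121), and that of H2-Ab1 also without Ctrl 2 (0.0859).

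RTI-treated mG-cKD showed no gene past the threshold against Ctrl in limma, with 625 at an unadjusted p under 0.05. C4b had a log2 difference of 0.54 ± 0.27 (adjusted p = 0.927), carried by mG-cKD RTI 1 at 6.75 FPKM, and of 0.09 without that library. The smallest p-values were those of Gm42669 (0.73 ± 0.13), Gm39822 (-0.87 ± 0.17), Sema7a (-0.62 ± 0.13), Tspan11 (-0.78 ± 0.16) and Myl1 (1.01 ± 0.22). The oligodendrocyte median was -0.53 with 0 of 15 called and 0 adjusted over the list alone (adjusted p = 1.1e-06, and adjusted p = 0.481 with an estimated correlation). The count was 2 without mG-cKD RTI 1 and 1 without Ctrl 2. Xist was read in mG-cKD RTI 2 and 3, at 16.1 and 30.8 FPKM, and in no Ctrl library above 0.01 FPKM.

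Across 16420 genes, which are not independent replicates, the mG-cKD and mG-cKO differences from Ctrl had a Pearson r of 0.388, where sharing the Ctrl libraries alone gave 0.499 (0.458 to 0.537) in simulated data without effects. The RTI difference and the genotype difference had an r of -0.234 in mG-cKD and -0.279 in mG-cKO, where shared libraries alone gave -0.499 (-0.53 to -0.469) and -0.5 (-0.534 to -0.468). The covariances were 0.0214, -0.0086 and -0.021, against simulated values of 0.0293, -0.0293 and -0.0294. All 3 correlations lay nearer to 0 than the simulated ranges. The simulated libraries were independent, whereas real P21 libraries of the same number correlated in part, so this cannot decide whether the effects are shared.

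The genes called at P45, an age whose libraries are separate from those of P21, were followed through the P21 groups. The 126 genes higher at P45 had a mean log2 level of 1.70 to 1.73 in the Ctrl libraries, 1.74 to 1.81 in mG-cKD, 2.84 to 3.13 in mG-cKO and 2.57 to 2.83 in RTI-treated mG-cKO. The 88 genes lower at P45 had means of 3.41 to 3.48 in Ctrl, 3.13 to 3.28 in mG-cKD, 1.98 to 2.10 in mG-cKO and 2.18 to 2.48 in RTI-treated mG-cKO. Against Ctrl, 83 of the 88 lower genes were below 0 in mG-cKD, with a median of -0.26 (camera p = 3.2e-04 with an estimated correlation), and the 126 higher genes had a median of 0.01 (p = 0.571 with an estimated correlation). In mG-cKO, 94 of the 126 higher genes were lower with RTI (p = 0.0125 with an estimated correlation) and 72 of the 88 lower genes were higher (p = 0.015). An exact two-sided permutation test of the mean between RTI-treated and untreated mG-cKO gave p = 0.1, the smallest that 3 against 3 libraries allow. These sets and tests were chosen after the data had been seen.

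**Figure D4:**
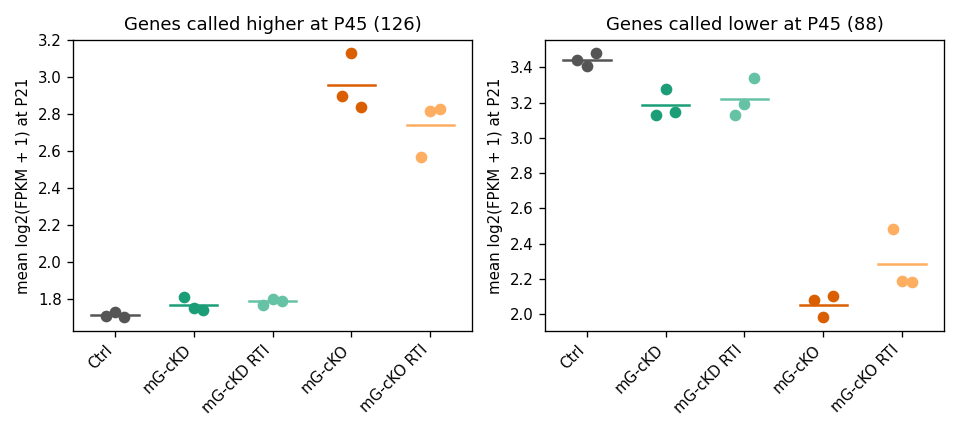
Mean log2 of FPKM with 1 added (vertical axis) in each P21 library over the 126 genes higher and the 88 genes lower in mG-cKO at P45, with 1 point per library and bars at the group means. In both panels every library of RTI-treated mG-cKO lay on the Ctrl side of every untreated mG-cKO library.

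At P1 the libraries labelled VPA were not alike, with a Pearson r over genes of 0.954 between VPA 1 and 2 and of 0.716 and 0.721 between these and VPA 3. C4b was at 0.955 and 1.20 FPKM in VPA 1 and 2, at 0.351 in VPA 3 and at 0.194 ± 0.004 in CT (n = 3), a log2 difference of 0.59 ± 0.22 (adjusted p = 0.188) that passed without VPA 3 (0.80, adjusted p = 0.0465). Prm1 was at 9.07 and 6.65 FPKM in VPA 1 and 2, listed at 0 in VPA 3 and at 0.38 to 0.65 in CT. The smallest p-values were those of Gm24840 (-2.72 ± 0.24), Mir128-1 (-2.36 ± 0.22), Mir6979 (-1.74 ± 0.16), Gm3375 (2.62 ± 0.24) and AC154408.2 (-1.43 ± 0.15), all short, noncoding or pseudogene entries, with adjusted p from 0.0686 to 0.0729. Immediate early genes had a median of 0.76 with 0 of 11 called and 10 adjusted over the list alone (adjusted p = 6.7e-04, and adjusted p = 0.559 with an estimated correlation). Of 11264 genes 0 passed in limma and 2644 had an unadjusted p under 0.05. Without CT 3 the count was 302 and without VPA 3 it was 179. The median difference of all genes was 0.12 and moved by -0.10 with libraries scaled to a common median, so directions in this table are relative to that shift. The values of VPA 3 lack the whole read steps of the other 5 libraries.

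**Figure D5:**
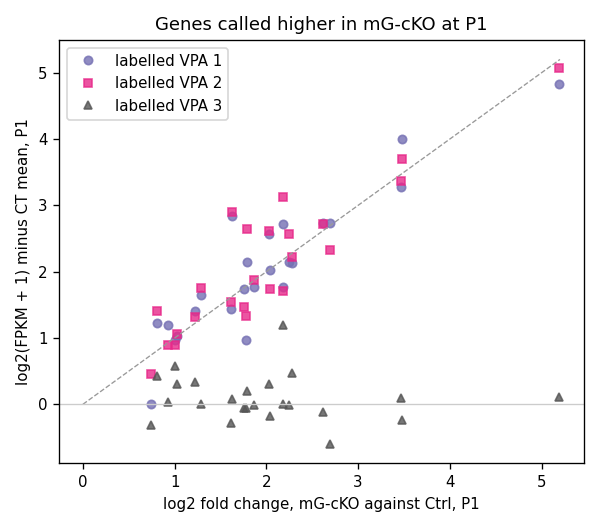
For the 24 genes higher in mG-cKO at P1 that the VPA table holds, the log2 difference in mG-cKO (horizontal axis) and the log2 difference of each library labelled VPA from the CT mean (vertical axis), with a dashed line where both are equal. The medians were 1.90 in VPA 1, 1.81 in VPA 2 and 0.01 in VPA 3.

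The 3 NPC libraries had no comparison group. They held progenitor genes at high levels, with Fabp7, a lipid-binding protein of radial glia, at 1628 ± 749 FPKM (n = 3) and Rrm2, a subunit of ribonucleotide reductase, at 177 ± 87.6. Of the astrocyte list Mlc1 was at 158 ± 21.4 and Acsbg1 at 146 ± 50.9. Nrgn and Tle4 of the excitatory neuron list were at 45.03 ± 22.1 and 25.7 ± 16.7, Sall1 of the homeostatic microglia list at 13.3 ± 5.96, and Cnp and Trf of the oligodendrocyte list at 48.2 ± 9.21 and 5.96 ± 6.94. The named genes are the highest of each list. A mean of 1 FPKM or more was reached by 18 of 20 measured progenitor genes and 14 of 15 astrocyte genes. It was reached by 6 of 14 excitatory neuron, 3 of 11 homeostatic microglia and 6 of 15 oligodendrocyte genes. C4b was at 0.50, 0.32 and 0.02 FPKM. The columns are headed C1 to C3 rather than with sample titles, and the values of C3 lack the whole read steps of the other 2.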

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

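Tests of shared reads in the C4b region, of matched random lists and of VPA 3 against Ctrl 3, and of the share of the mG-cKO effect lost under RTI were chosen after the results were seen.

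The effect of mG-cKO differed between P45 and P1 for 71 genes, by the test of the difference between both ages. The make-up by sex also differed between these ages. The named ones that gained were C4b (2.10), Tmc1 (1.93), Fgf21 (1.76), Pcdha1 (1.59), Fabp7 (1.56), Pcdhga8 (1.56), Stc2 (1.35), P2rx7 (1.27), Rps16 (0.83) and Aqp4 (0.80), as log2 differences of the effects. Those with a lower effect at P45 than at P1 were Cldn11 (-2.77), Mal (-2.12), Ermn (-2.09), Opalin (-1.87), Tmem88b (-1.87) and Hapln2 (-1.81), and the oligodendrocyte list had a median of -2.01. Some myelin genes were low in Ctrl at P1, which left little room for a fall there. The calls of Aqp4 and Rps16 ended without most single libraries (adjusted p up to 0.134 and 0.171), with scaled libraries (0.115 and 0.431) and with a pseudocount of 0.1 (0.0581 and 0.0754). Of 100 drawn splits of the libraries 11 gave as many genes, with 10656 in the highest other, so chance cannot be excluded by that count. Such large splits point to a structure of the samples. For mG-cKO at P45 the larger splits put both replicate 3 libraries on the same side, and which libraries the interaction splits joined was not traced. Of the 15 splits that part all pairs 1 gave as many, the real one, and the highest other gave 65.

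In the C4b region, C4b, Stk19-ps1 and Skiv2l-ps1 rose at P21 by 3.04, 3.33 and 2.38, and Tnxa, below the filter there and untested, differed by 0.64, under the bound of 1 that had been set for it. Reads spilling over from near-identical copies are argued against: Stk19 and Skiv2l were at 24.2 and 17.9 FPKM in Ctrl, where Stk19-ps1 and Skiv2l-ps1 were listed at 0, and C4a, at 0.55 with no overlap of the groups, reached 1.51 FPKM in mG-cKO against 22.9 of C4b (median of these copies and of Tnxb, which is below the filter and untested, 0.058). A rise of the whole region is argued against by the 28 other genes within 200 kb, with 0 called in limma and a median of 0.051. No biological explanation was tested. Reads that align equally well to several copies, and how they were assigned, remain open.

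The genes higher in mG-cKO at P1 were also high in VPA 1 and 2, with medians of 1.90 and 1.81 over CT against 1.83 in mG-cKO, and not in VPA 3 (0.01). A difference in quantification or library that acts on all genes of like expression is argued against, since 0 of 10000 lists matched on expression were as high (highest 0.443). The lists were not matched on the type of gene, and many of these genes are Gm, Rik or AC entries. A difference confined to such entries remains open. Tissue of mG-cKO under a VPA label did not show what it needed in the genes lower at P1 with the block, the part not seen before: 38.9% of them lay below CT in VPA 1 and 2 (exact 95% interval 23.1% to 56.5%), not over 65%, and 46.7% of all genes did, while the slope of 0.791 over all genes called so includes those that raised the question. It is still not excluded, because the interval, brought in after the share was seen, crosses the bound of 55% set for that. These 36 lower genes had a median difference of only -0.468 at P1 with the block. Over 10653 genes, those that raised the question included, VPA 1 and 2 had an r of 0.927 to 0.935 with mG-cKO 1 and 2 of P1. With Ctrl 1 and 2 of P1 it was 0.917 to 0.925. The CT libraries had 0.823 to 0.914 and 0.821 to 0.917, and VPA 3 had 0.924 with mG-cKO 3 and 0.928 with Ctrl 3. VPA exposure could also underlie the pattern, though VPA 3 differed from Ctrl 3 of P1 by a median of only 0.036, and the values of VPA 3 lack whole read steps, so these cannot be told apart.

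Over the genes called at P45, RTI-treated mG-cKO at P21 had lost 17.2% of the mG-cKO effect. A chance shift from choosing genes on the shared mG-cKO libraries is argued against, because the genes were chosen at P45, in other libraries. A single library is argued against as the whole source, since without mG-cKO RTI 1 the share was 10.3%, although that library moved it by over 1.5 times. The share without both mG-cKO 2 and mG-cKO RTI 1 was not computed. Over the higher genes these were at 3.13 and 2.57. The other untreated mG-cKO libraries were at 2.90 and 2.84 and the other RTI libraries at 2.82 and 2.83, so that shift rested largely on those libraries. Over the lower genes the others were at 2.08 and 2.10 untreated and at 2.19 and 2.18 with RTI. Whether RTI lowers the mG-cKO effect in part thus stays open. Xist was at 27.1 and 36.4 FPKM in mG-cKO RTI 2 and 3 and at 0.04 or less in the untreated mG-cKO libraries. The exact two-sided permutation p of 0.1 is the smallest possible.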

How the results depend on the processing

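The covariate for whole read steps, whole-read libraries, untreated groups with the block and leaving out 2 libraries apart in Rn7sk and C4b were chosen after seeing the data. Of 270 named calls 212 held without any single library. Without trend and robust estimation every count stayed within 1.5 times. For mG-cKO against Ctrl, counts at P1, P7, P14 and P45 were 28, 32, 68 and 228. They became 7, 11, 161 and 0 in fits of the compared groups alone, which have fewer libraries for the variance, and 181, 299, 895 and 2740 with the replicate block, of which 168 were higher and 131 lower at P7 and 333 and 562 at P14. Whole-read libraries alone gave 77, 403, 1166 and 2345, no filter gave 74 at P7, 136 at P14 and 368 at P45, and the covariate 361 at P1 and 3301 at P45. Leaving out 1 library gave 13 to 20, 15 to 17, 36 to 42 and 161 to 287. For age in Ctrl (7221) the groups alone gave 3353, the block 13885, the covariate 14079, whole-read libraries 15341 and leaving 1 out 5600 to 10556. For the age interaction (71) a pseudocount of 0.1 gave 42, the groups alone 11, the block 1038, the covariate 1391, whole-read libraries 822 and leaving 1 out 39 to 85. The cause was not tested. At P21 the untreated groups with the block gave 587 for mG-cKO against Ctrl (leaving 1 out 246 to 314) and 379 against mG-cKD (156 to 215). For RTI in mG-cKD (0 in limma, 353 at unadjusted p under 0.05) no filter gave 1, the groups alone 2 and leaving out both libraries 1. For RTI in mG-cKO (1) a pseudocount of 0.1 gave 0, no filter 7, the groups alone 0, both libraries out 0 and 1 out 0 to 2. For RTI-treated mG-cKD (0) no filter gave 2, the groups alone 1, both out 3 and 1 out 0 to 2. For RTI-treated mG-cKO (377) the groups alone gave 144 and 1 out 177 to 502. For the RTI interaction (0) no filter gave 2, both out 1 and 1 out 0 to 1. Leaving 1 out gave 0 to 1 for mG-cKD and 0 to 302 for VPA. The block ended 3 named calls, those of H2-Q4 (adjusted p = 0.0526) and Hes1 (0.0553) against mG-cKD and of H3c15 (0.0542) in RTI-treated mG-cKO. List calls went from 182 to 14 with an estimated correlation. Shared differences moved to 0.346, -0.297 and -0.255 with a pseudocount of 0.1. C4b in mG-cKD (0.01) reversed to -0.01007 with scaled libraries, and lay from -0.08379 to 0.0799 with 1 library out. Unknown depth in 21 libraries limits what low genes can show.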

Other observations

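The tests of genes raised at every age and of neighbouring genes were chosen after the results were seen.

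Of the genes raised in mG-cKO at all 5 ages there were 13, of which 6 had a symbol other than Gm or AC and a number or Rik: Prm1, Mnd1, Gramd1c, Stag3, Tcfl5 and Hamp2. Of these, Prm1 was also at 5.40 ± 2.09 FPKM in mG-cKD at P21 against 0.09 ± 0.16 in Ctrl, a difference that did not pass. Tcfl5 and Mnd1 were at 0.47 and 0.49 FPKM in mG-cKD against 0.36 and 0.60 in Ctrl. Prm1 thus differed from them in mG-cKD, and why was not tested. Genes called higher at P21 lay within 50 kb of each other in 17 pairs, where 1000 random sets of tested genes gave a mean of 1.40 and at most 6, and 16 pairs were left without protocadherins. At P45 the higher genes gave 6 pairs against a mean of 0.464 and at most 4. The lower genes gave 3 pairs at P21 (at most 4 in random sets) and 1 at P45 (at most 3).

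Other splits of the compared libraries were counted for each comparison with 3 libraries per group, where 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 28 and 5 for mG-cKO at P1 (1 split as large, the real one), 360 and 1 for mG-cKO at P21 (1), 251 and 1 for mG-cKO against mG-cKD (1), 7221 and 0 for age in Ctrl (1), and 1 and 0 for RTI in mG-cKO (1). For mG-cKO at P45 they were 228 and 4354 (5 splits as large), where larger splits put both replicate 3 libraries on the same side. Splits that part all pairs gave at most 0 there besides the real one, and 2740 passed with the block. They were 377 and 1324 for RTI-treated mG-cKO (2), the larger one setting Ctrl 1, Ctrl 3 and RTI 1 against the rest. The former had FPKM sums of 401206 to 421747 and the rest 344637 to 350145. For RTI-treated mG-cKD they were 0 and 874 (10), the other split setting Ctrl 1, Ctrl 3 and RTI 2 against the rest. Its RTI 2 had a sum of 380592, against 369718 and 351121 in RTI 1 and 3. Both splits follow this structure of the samples, which sets Ctrl 1 and 3 apart from Ctrl 2. It bears on each comparison against Ctrl at P21. The real and highest other counts were 0 and 1 for mG-cKD (10), 0 and 1 for RTI in mG-cKD (10), and 0 and 0 for VPA (10), all in limma. For the difference of the RTI effects all 100 drawn splits gave as many as the real 0, with 2 at most. Where the real count was 0 every split gives as many, so these counts decide nothing.

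Rn7sk was at 152 FPKM in mG-cKO 2 of P21 and at 44.9 in mG-cKD RTI 1, against 22.3 or less in the other P21 libraries. Ttr, a choroid plexus gene, ranged from 1.44 to 508 FPKM among the P21 libraries.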
